A study of Homo sapiens with 12 samples.

How the data were processed

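The series holds 12 expression arrays of HCC827 cells, an established human lung adenocarcinoma line that carries an activating EGFR mutation, and of cells derived from it. The labels give 4 groups of 3 arrays: the parental line, ERC4 cells described as resistant to erlotinib, an inhibitor of the EGFR kinase, cells transduced with a lentivirus for a non-target shRNA (NT), and cells transduced with a lentivirus for an shRNA against EGFR (EGFRsh). Per the labels, all cells grew in medium with 5% FBS, and NT and EGFRsh cells also with 5 ug/ml puromycin. Groups were taken from the sample titles and descriptions, since one characteristic of the labels calls all 12 samples resistant, the parental ones included. Nothing in the labels says whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

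The deposited values are intensities of 22277 probe sets per array, on a linear scale. They were made with RMA, per the submitters' processing notes, and its version and which arrays were processed together are not given in the sources used here. Array medians lay between 50 and 53 in the parental and ERC4 arrays and between 141 and 143 in the NT and EGFRsh arrays, as 2 separately normalized sets of 6 arrays would. The comparisons of ERC4 with parental and of EGFRsh with NT each lie within a set. Hybridisation controls, which are added to the sample, still differed between compared groups. Their mean log2 level was 10.75 in parental and 9.16 in ERC4, and 11.04 in NT and 11.65 in EGFRsh. Differences in handling between compared groups are thus not ruled out. NT minus parental runs between the sets, so that group and set cannot be told apart there, and the difference between effects compares changes measured in sets of unequal spread. The mean SD of the log2 values was 1.89 in the first set and 2.26 in the second.

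The design fixed beforehand had assumed log2 values, so the deposited intensities were taken to log2(value + 1) first, which understates fold changes of dim genes. Of the probe sets, 19070 carried 1 gene symbol in the platform annotation, 1043 carried several and 2164 none, and only those with 1 symbol were named. Where several probe sets belonged to a gene, the one with the highest mean over all 12 arrays stood for it, which gave 11963 genes. Of the 4310 genes with several probe sets, 321 had probe sets called in opposite directions in ERC4 minus parental and 366 in EGFRsh minus NT. Gene order along the chromosomes came from a RefSeq table of GRCh38.p14 and was used only to find neighbouring genes.

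Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 model for all 12 arrays, 8 residual degrees of freedom). Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and calls of at least 2-fold were counted too. All adjusted p-values for genes are from limma and two-sided. Errors of log2 fold changes are limma's standard errors. Gene lists, 26 in number, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 104 tests of lists by contrasts, and again with an estimated correlation. These 26 lists, the limma and camera tests and most alternatives were fixed before the data were examined. Some tests of explanations and a hepatocyte marker list were chosen later, as stated where they are reported.

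The genes named are EGFR, then in each contrast the 10 highest and 10 lowest log2 fold changes among called genes whose replicates did not overlap and whose higher group mean reached the median of all log2 values, 6.37. The difference of effects took 5 in each direction with no demand on overlap, and shared calls took the 5 in each direction with the largest smaller change. Up to 4 called members of each list, and members of the ERBB, mesenchymal and bypass kinase lists whether called or not, complete the rule.

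The procedure was tested on simulated data of 11963 genes, of which 80 were changed by 0.5 on the log2 scale, 80 by 1 and 40 by 2, far fewer than were called in the real arrays. For ERC4 minus parental it recovered 75.0% of genes changed by 0.5 on the log2 scale, 98.8% at 1 and 100% at 2, with 4.79% false among calls. For EGFRsh minus NT it recovered 76.2%, 100% and 100%, with 3.72% false among calls.

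Alternatives covered the replicate number as a block, fits of only the compared arrays, eBayes with trend and robust settings, array weights, quantile normalization, median centring, a filter on dim genes, the mean of a gene's probe sets, every probe set on its own, a threshold of 0.01 and leaving out each array. A transform with no pseudocount, quantile normalization within each set, stretching the parental and ERC4 values to the spread of the other set, and list tests on 6 arrays were added after seeing the data. The number of arrays, 3 per group, limits the precision. Exact tests of 3 arrays against 3 cannot give a p under 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.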

Results

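Transcript levels were measured on 12 arrays of HCC827 lung adenocarcinoma cells in 4 groups of 3: parental cells, erlotinib-resistant ERC4 cells, cells with a non-target shRNA (NT) and cells with an shRNA against EGFR (EGFRsh). Replicate arrays of a group correlated at 0.9923 or above across probe sets. The series title names EGFR inhibitor resistance as its subject, and the design allows resistant cells to be set against their parental line, EGFR-depleted cells against their vector control, and both changes against each other.

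EGFR, the target of the drug and of the shRNA, was examined first. Its transcript (probe set 201983_s_at) had a log2 level of 12.38 ± 0.04 (SD, n = 3) in parental, 12.60 ± 0.09 in ERC4, 13.55 ± 0.10 in NT and 12.25 ± 0.09 in EGFRsh cells. In EGFRsh it fell by 1.30 ± 0.07 (SE) on the log2 scale against NT, a 2.46-fold decrease (limma adjusted p = 2e-09). The other bright EGFR probe sets gave larger log2 changes, of -2.16 (201984_s_at), -2.70 (210984_x_at) and -2.72 (211607_x_at). In ERC4 the transcript was higher by 0.21 ± 0.07 (adjusted p = 0.025), a call that ended after quantile normalization (0.16) and without ERC4 replicate 2 (0.16) or parental replicate 2 (0.19). In ERC4 the probe set 201984_s_at gave a larger increase of 0.66 ± 0.09 (adjusted p = 2.2e-05), while 210984_x_at (0.27) and 211607_x_at (0.26) were not called (adjusted p = 0.062 each). The difference of effects for EGFR was 1.51 ± 0.10 (limma adjusted p = 3.5e-08). Since EGFR is the target of the shRNA, this mostly restates its fall in EGFRsh.

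**Figure D1:**
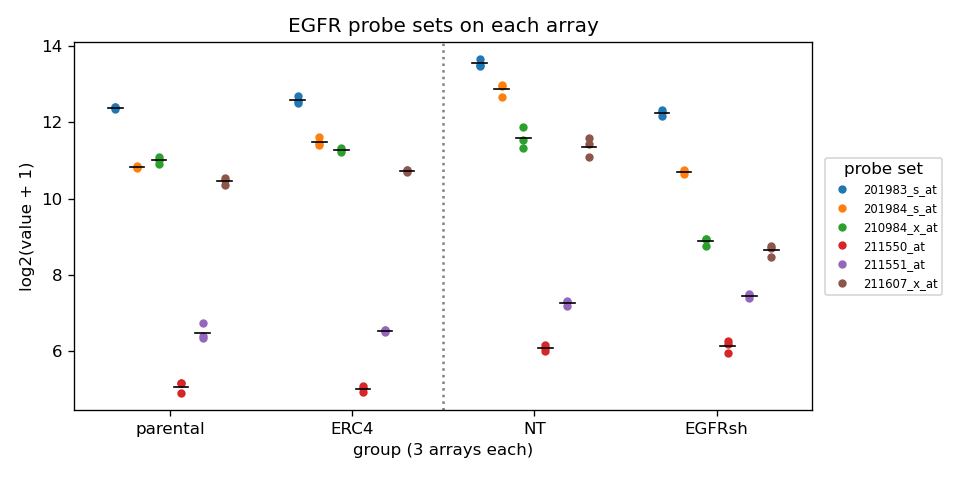
Log2(value + 1) of the 6 EGFR probe sets on each of the 12 arrays, by group; points are arrays, black bars group means, and the dotted line parts the 2 sets of arrays. The probe set 201983_s_at lies at 13.55 in NT and 12.25 in EGFRsh on average, while 211550_at and 211551_at stay below 8 in every group.

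In ERC4 against parental cells, the most increased transcript was SPP1, which encodes the secreted phosphoprotein osteopontin, at 52.9-fold (5.72 ± 0.09 on the log2 scale). FGG and ALB, which encode the plasma proteins fibrinogen gamma and albumin, rose 16.8-fold and 9.85-fold. VIM, encoding the mesenchymal intermediate filament vimentin, rose 8.86-fold, and IGFBP1 rose 14.0-fold. The secreted iron-carrier protein gene LCN2 fell by 4.88 ± 0.06, and S100A9, which encodes a calcium-binding inflammatory protein, fell by 4.31 ± 0.11. The tight junction gene CLDN7 and the epithelial splicing regulator ESRP1 fell by 3.90 ± 0.08 and 3.85 ± 0.14. SPOCK1, POGLUT2, TMEM158, DUSP1 and PLK2 completed the 10 largest increases, and SH3YL1, SPRR1B, GALNT3, TCN1, TMPRSS11E and SCNN1A the 10 largest decreases. The adjusted p-values of these 20 genes were 1.5e-09 or lower. In 14 of them, SPP1 (4.41 in parental) and ALB (3.62) included, the lower group lay under its array medians, so that fold sizes and ranks rest on dim signal there.

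Of the 24 measured epithelial junction and identity genes, 23 fell in ERC4 and 1 was not called, both over all genes and adjusted over the list alone (median -1.89; camera adjusted p = 4.9e-16, and adjusted p = 0.00063 with an estimated correlation). RAB25 fell 8.49-fold and the adhesion gene CDH1, encoding E-cadherin, fell 6.73-fold. The mesenchymal list did not shift as a whole, with 5 of 27 members higher, 10 lower and 12 not called (adjusted p = 0.53). Its 2 members that rose by at least 2-fold were VIM and ZEB1, a transcriptional repressor of epithelial genes, at 2.94-fold.

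Of 25 mitosis genes, 17 were higher in ERC4 and 0 lower, 18 adjusted over the list alone, with KIF20A at 2.59-fold and TTK at 2.48-fold (camera adjusted p = 2.9e-05, but adjusted p = 0.11 with an estimated correlation). Among DNA replication genes, 17 of 25 were higher and 4 lower, CDC6 by 2.59-fold, with the same counts adjusted over the list alone (adjusted p = 0.0084, and adjusted p = 0.33 with an estimated correlation). YAP and TEAD targets were higher in 13 of 18 cases and lower in 3, 4 adjusted over the list alone, with AMOTL2 at 5.14-fold and CCN1 at 3.72-fold (adjusted p = 0.019, and adjusted p = 0.11 with an estimated correlation). Of the unfolded protein and amino acid stress genes, 13 of 23 were higher and 3 lower, VLDLR by 4.92-fold, while DDIT4 fell by 1.36 (adjusted p = 0.011, and adjusted p = 0.11 with an estimated correlation). Squamous and basal genes were lower in 12 of 17 cases, SPRR1B by 11.9-fold (adjusted p = 0.00019, and adjusted p = 0.11 with an estimated correlation), and lung secretory and alveolar genes in 10 of 21, 13 adjusted over the list alone, MUC1 by 6.86-fold (adjusted p = 0.015, and adjusted p = 0.089 with an estimated correlation). Glycolysis genes were higher in 10 of 19 cases, but the list passed the threshold only before rounding (adjusted p = 0.05, and adjusted p = 0.3 with an estimated correlation), and leaving out any of 9 of the 12 arrays ended the call. Over all 11963 genes, 3453 were called higher and 3449 lower. Of the 3988 genes brightest by mean signal, 2106 were called higher and 669 lower. That share of higher calls is near those of the stress and glycolysis lists.

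Receptors and ligands known from bypass of EGFR inhibition moved singly. The ERBB ligand gene NRG1 rose 3.20-fold with probe sets that disagreed in direction, and the receptor gene ERBB3 fell 3.96-fold. KIT fell 2.68-fold, PROS1 rose 2.31-fold and VEGFA by 1.00 on the log2 scale. The brightest probe sets of MET (-0.08 ± 0.08) and AXL (-0.21 ± 0.09) were not called, but the other MET probe sets were called lower, at -0.37 (211599_x_at), -0.40 (213807_x_at) and -0.51 (213816_s_at). A second AXL probe set (202686_s_at) gave 0.95 ± 0.13. Probe sets of FGFR1 were called in opposite directions, at 0.32 (207937_x_at, the brightest), 0.75 (210973_s_at) and -0.71 (215404_x_at). Neither the ERBB list (adjusted p = 0.9) nor the bypass kinase list (adjusted p = 0.37) shifted as a whole.

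In all, 6902 of 11963 genes were called in ERC4 minus parental, 3453 higher and 3449 lower, of which 539 were higher and 214 lower by at least 2-fold. The share of calls that were higher, 50%, depended on the processing. It was 60.4% without dim genes, 59% after median centring and 46.1% after quantile normalization over all 12 arrays. The 3 arrays of each group did not overlap in 60.5% of genes, against 10% by chance. Small changes followed signal level: of the 3 equal parts of the genes by mean signal, a grouping chosen after the data were seen, 86.1% of calls were lower in the dimmest and 24.1% in the brightest. Leukocyte markers, 9 of 18 of which were lower, 8 adjusted over the list alone (adjusted p = 0.015, and adjusted p = 0.19 with an estimated correlation), lost their call after quantile normalization within the set (adjusted p = 0.13), as did DNA replication (adjusted p = 0.17), glycolysis (adjusted p = 0.21) and stress genes (adjusted p = 0.081). Leaving out dim genes ended the calls for DNA replication (adjusted p = 0.11), glycolysis (adjusted p = 0.22), YAP targets (adjusted p = 0.18) and stress genes (adjusted p = 0.11).

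In EGFRsh against NT cells, the most increased transcript was NNMT, which encodes nicotinamide N-methyltransferase, at 62.0-fold (5.95 ± 0.08). Its log2 level was 9.65 in parental, 6.85 in NT and 12.8 in EGFRsh cells. A low NT level may thus make up part of this change, though parental cells lie in the other set of arrays. TAGLN, encoding the actin-binding protein transgelin, rose 50.9-fold, and the matrix genes THBS1 and SPARC rose 31.1-fold and 28.7-fold. CDH1 fell 77.6-fold (-6.28 ± 0.10), CDH3 48.0-fold and EPCAM, an epithelial adhesion gene, 30.3-fold. PLAC8, EMP3, FZD7, EVI2A, ADAM19 and PTX3 were the other large increases, and CEACAM6, SCNN1A, TMEM30B, SPRR3, SCEL, PRODH and AGR2 the other large decreases. CEACAM6 and SPRR3 were also among the genes highest in NT minus parental. The adjusted p-values of these 20 genes were 1.4e-11 or lower, and in 19 of them the lower group lay under its array medians, with the same limit on fold sizes and ranks.

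All 24 measured epithelial genes fell in EGFRsh (median -2.76; adjusted p = 3.5e-21, and adjusted p = 0.00042 with an estimated correlation), and the result was the same adjusted over the list alone. Of the 27 mesenchymal genes, 17 rose, 15 of them by at least 2-fold, and 2 fell (adjusted p = 3.3e-07, and adjusted p = 0.0086 with an estimated correlation). COL5A1 rose 18.8-fold and COL6A1 13.8-fold. Fibroblast and endothelial markers, the list for cells of another type, were higher in 2 of 18 cases and lower in 3 (adjusted p = 0.93). ZEB2 and SNAI2, both transcriptional repressors of epithelial genes, had log2 fold changes of 2.87 ± 0.15 and 2.59 ± 0.13. The array's control probe sets for ACTB gave a 3' minus 5' log2 signal of 1.07 ± 0.15 (SD) in EGFRsh and 0.20 ± 0.03 in NT, an excess of 0.87, and those for GAPDH an excess of 0.35 (exact permutation p = 0.1 each, two-sided, the smallest possible).

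**Figure D2:**
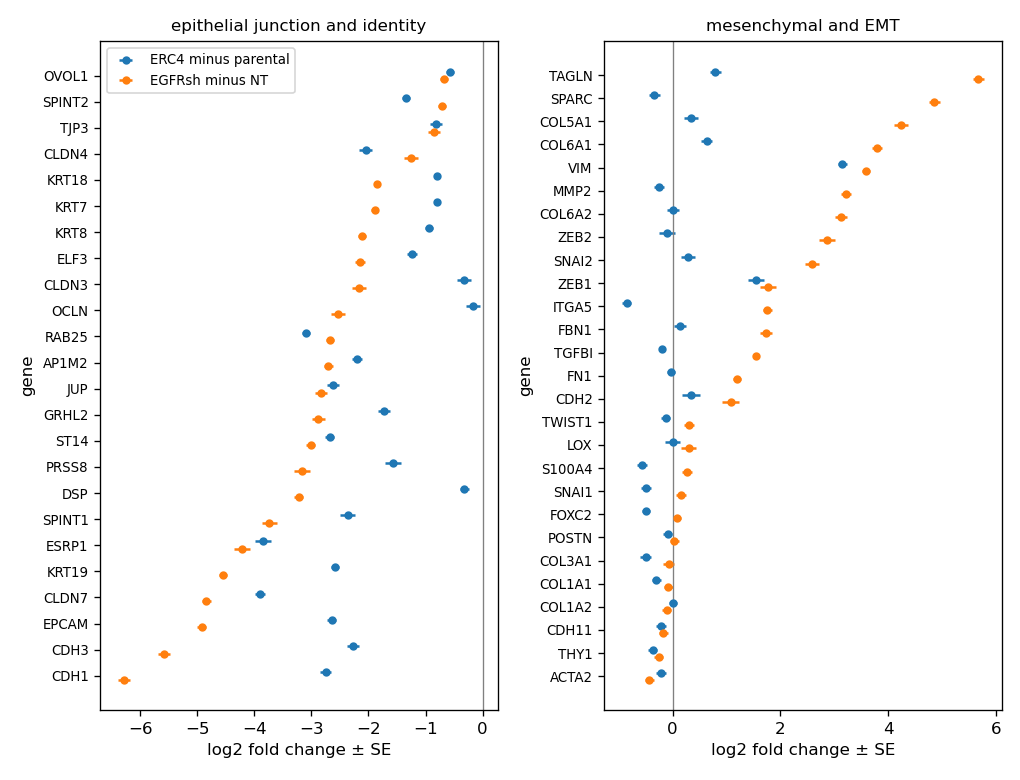
Log2 fold change ± SE (limma) of each measured epithelial (left) and mesenchymal (right) gene in ERC4 minus parental (blue) and EGFRsh minus NT (orange), 3 arrays per group. Epithelial genes lie below 0 in both comparisons, with medians of -1.89 and -2.76, and 15 of the 27 mesenchymal genes rose by at least 2-fold in EGFRsh minus NT.

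Interferon response genes were lower in EGFRsh than in NT in 24 of 28 cases, 18 of them by at least 2-fold, and 1 was higher (median -1.63; adjusted p = 5.4e-11, but adjusted p = 0.089 with an estimated correlation). IFI27 fell 15.9-fold, OAS1 11.9-fold and the antiviral GTPase gene MX1 9.78-fold. The ACTB control excess of 0.87 went with this group too. NF-kB and inflammatory cytokine genes rose in 17 of 25 cases, 18 adjusted over the list alone, and fell in 5 (adjusted p = 0.00071, and adjusted p = 0.025 with an estimated correlation). Within it CXCL6 rose 19.6-fold, CXCL8 8.22-fold and IL6 7.49-fold, and LCN2 fell 9.33-fold.

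YAP and TEAD targets rose in 14 of 18 cases, CCN2 by 20.5-fold and ANKRD1 by 8.21-fold (adjusted p = 3.5e-05, and adjusted p = 0.02 with an estimated correlation). TGF-beta signalling genes rose in 12 of 22 cases, 13 adjusted over the list alone, with INHBA at 6.12-fold and TGFB1 at 5.33-fold (adjusted p = 0.00071, and adjusted p = 0.025 with an estimated correlation). Lung secretory and alveolar genes fell in 15 of 21 cases, LPCAT1 by 10.5-fold (adjusted p = 0.00011, and adjusted p = 0.02 with an estimated correlation). Cholesterol synthesis genes fell in 12 of 16 cases, INSIG1 by 2.07-fold (adjusted p = 0.00037, and adjusted p = 0.025 with an estimated correlation). DNA replication genes fell in 18 of 25 cases, 19 adjusted over the list alone, MCM7 by 2.75-fold (adjusted p = 0.00038, but adjusted p = 0.22 with an estimated correlation). Relative to the median of all genes, the DNA replication list lay 0.97 above parental cells in NT and 0.63 above them in EGFRsh. The cholesterol synthesis list lay at 0.46 in NT and -0.04 in EGFRsh. For both lists, whether EGFRsh or NT departed cannot be told, since parental cells lie in the other set of arrays. The ACTB and GAPDH control excesses were present in the same EGFRsh arrays.

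DUSP6, a phosphatase gene induced by MAPK signalling, was 18.8-fold lower in EGFRsh than in NT. The MAPK output list was not called (5 of 18 higher and 7 lower, camera adjusted p = 0.55). The log2 level of DUSP6 was 6.44 in parental, 11.91 in NT and 7.68 in EGFRsh cells. Relative to the median of all genes, it was 4.03 higher in NT than in parental cells. Whether EGFRsh or NT departed cannot be told, since parental cells lie in the other set of arrays. ERBB3 fell 14.8-fold and ERBB2 4.59-fold, while HBEGF rose 3.98-fold and NRG1 3.72-fold. IGFBP2 fell 14.0-fold and FGF9 4.19-fold, and PDGFA rose 3.99-fold. MET differed between its 4 probe sets: the brightest gave 0.16 ± 0.08 and was not called, while the other 3 were called lower, at -1.80 (211599_x_at), -1.73 (213807_x_at) and -1.09 (213816_s_at). AXL gave 0.31 ± 0.09 in its brightest probe set and 3.04 ± 0.13 in 202686_s_at. FGFR1 gave 0.26 ± 0.08 in its brightest probe set, 1.37 ± 0.09 in 210973_s_at and 2.32 ± 0.13 in 211535_s_at. In all, 5966 genes were called, 3022 higher and 2944 lower, with 585 higher and 492 lower by at least 2-fold, and the arrays did not overlap in 61.3% of genes, against 10% by chance.

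**Figure D3:**
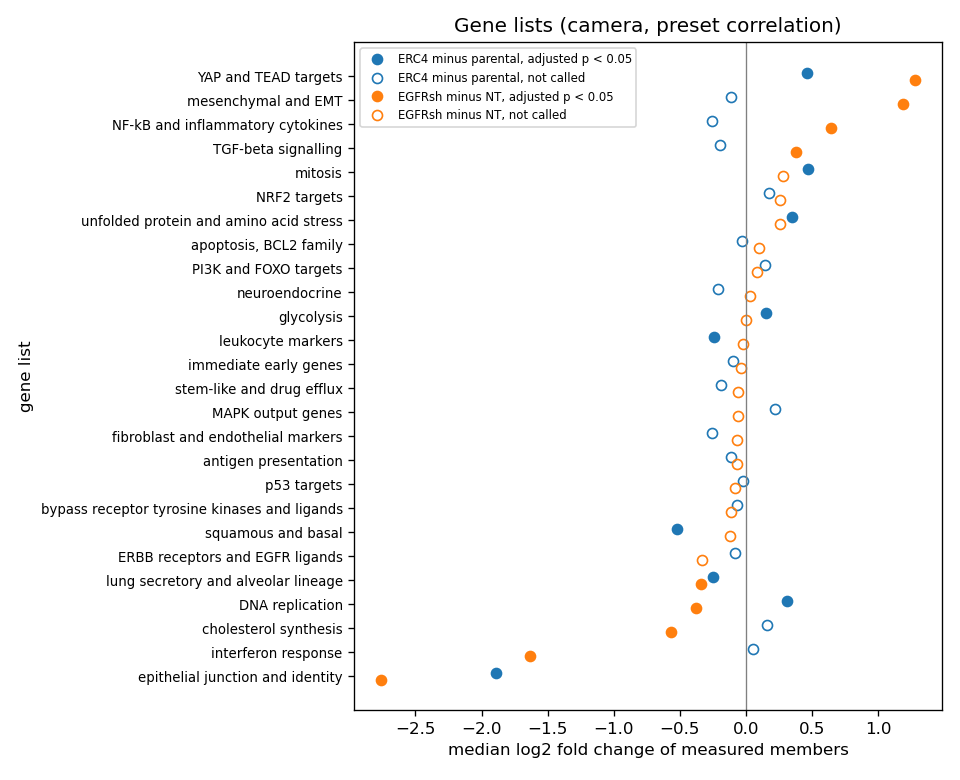
Median log2 fold change of the measured members of each of the 26 gene lists in ERC4 minus parental (blue) and EGFRsh minus NT (orange); filled points have a camera adjusted p under 0.05 at the preset correlation. The epithelial list is lowest in both, at -1.89 and -2.76, and the interferon list lies at 0.05 in ERC4 and -1.63 in EGFRsh.

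ERC4 and EGFRsh cells shared many changes. By the labels, all ERC4 arrays come from a single resistant line and all EGFRsh arrays carry a single shRNA label. Effects particular to that line or shRNA thus cannot be told apart from those of resistance or EGFR depletion. VIM, TMEM158, SPOCK1, P3H2 and DUSP1 led the transcripts that rose in both, VIM by 8.86-fold in ERC4 and 12.1-fold in EGFRsh. CLDN7, ESRP1, SPRR1B, TMPRSS11E and the sodium channel gene SCNN1A led those that fell in both, CLDN7 with log2 fold changes of -3.90 and -4.84. At 2-fold or more, 141 genes rose in both comparisons where independent lists would share 26.4, and 107 fell in both where they would share 8.80. Over all calls, 1609 rose and 1053 fell in both, 2662 together, against 872 and 849 for independent lists. The log2 fold changes correlated across genes, which are not independent replicates, at Pearson's r = 0.37 and Spearman's rho = 0.28. The comparisons share no arrays.

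**Figure D4:**
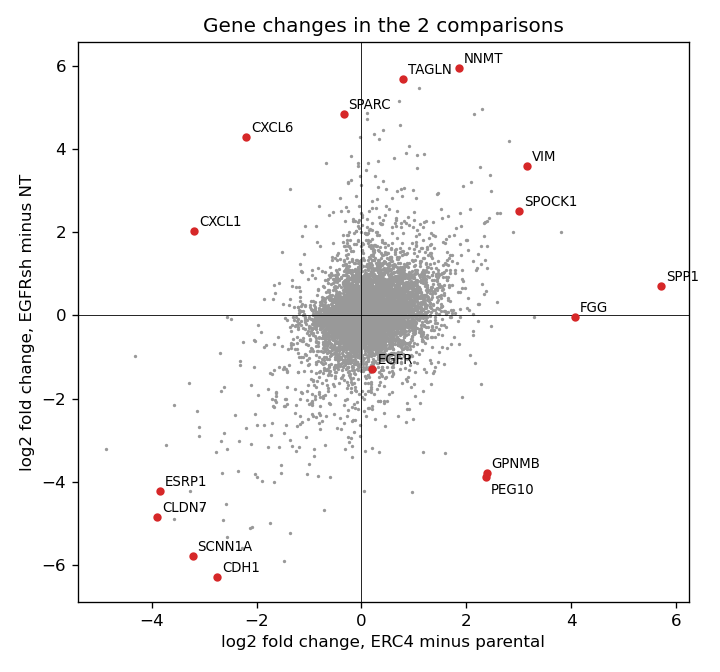
Log2 fold change of each of 11963 genes in ERC4 minus parental (horizontal) and EGFRsh minus NT (vertical); red points carry gene names. VIM and SPOCK1 lie high in both, CLDN7 and ESRP1 low in both, and GPNMB, PEG10, CXCL1 and CXCL6 in opposite corners.

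Other genes changed in opposite directions. PEG10 rose 5.18-fold in ERC4 and fell 14.8-fold in EGFRsh, and GPNMB, which encodes a transmembrane glycoprotein, rose 5.23-fold and fell 13.9-fold. The chemokine genes CXCL6 and CXCL1 fell 4.60-fold and 9.14-fold in ERC4 and rose 19.6-fold and 4.12-fold in EGFRsh. The EGFRsh changes are measured against NT. Log2 levels in parental, NT and EGFRsh cells were 8.11, 12.2 and 8.32 for PEG10 and 4.64, 9.85 and 6.05 for GPNMB. Relative to the median of all genes, NT minus parental was 3.76 for GPNMB and -3.42 for CXCL6. Whether EGFRsh or NT departed there cannot be told, since parental cells lie in the other set of arrays. KRT4 rose 3.04-fold in ERC4, where its probe sets disagreed in direction, and fell 9.87-fold in EGFRsh. SPP1 rose 52.9-fold in ERC4. Its 1.63-fold change in EGFRsh rests on dim signal, at log2 levels of 4.49 in NT and 5.19 in EGFRsh under array medians of 7.15 to 7.17. PLAAT4 rose 1.96-fold in ERC4 and fell 19.0-fold in EGFRsh. TAGLN rose 1.74-fold in ERC4 and 50.9-fold in EGFRsh. SPARC and FZD7 rose 28.7-fold and 29.0-fold in EGFRsh, with differences of effects of -5.18 and -4.75 on the log2 scale. In parental and ERC4 cells both were dim, at log2 levels of 3.81 and 3.47 for SPARC and 3.73 and 3.83 for FZD7 under array medians of 5.67 to 5.75, so that no change can be read between these cells. TAGLN also lay under these medians there (4.34 and 5.14). The test of the difference of effects called 5936 genes, 3053 with the higher log2 fold change in ERC4 minus parental and 2883 with the higher one in EGFRsh minus NT. Over all calls, opposite changes were less frequent than independent lists would give: 766 genes rose in ERC4 and fell in EGFRsh (850 for independent lists) and 389 did the reverse (871). At 2-fold or more these were 23 and 10 genes, close to the 22.2 and 10.5 of independent lists.

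The difference was also called for 10 gene lists. Epithelial genes fell less in ERC4 than in EGFRsh (median difference 1.07; camera adjusted p = 2.4e-06), and mesenchymal genes were shifted towards higher values in EGFRsh (median difference -0.74; adjusted p = 9.4e-09). The calls for the epithelial, mesenchymal, cholesterol, NF-kB and TGF-beta lists held with an estimated correlation, at adjusted p-values from 0.0058 to 0.025. Those for mitosis (adjusted p = 0.3), DNA replication (adjusted p = 0.11), glycolysis (adjusted p = 0.28), interferon (adjusted p = 0.11) and YAP targets (adjusted p = 0.11) did not. The 2 sets of arrays differ in spread, and after stretching to equal SD the YAP call ended (adjusted p = 0.11), while quantile normalization within sets ended those for mitosis (adjusted p = 0.21) and glycolysis (adjusted p = 0.074).

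NT against parental cells would show what transduction and puromycin go with, but here it runs between the 2 sets of arrays, and 11446 of 11551 called genes were higher, with a median of 1.45 over all genes. Relative to that median, the log2 fold change was 4.03 for DUSP6, 3.05 and 2.90 for the interferon-induced genes IFIT1 and MX1, and 2.79 or more for CLIC2, GPNMB, SPRR3, RGCC, CEACAM6, CEACAM5 and BTBD3, which with these were the highest. SERPINB4 and SERPINB3, which encode serpin protease inhibitors, were lowest, at -5.97 and -5.45 relative to the median. NNMT, FGB, S100A9, CXCL6, S100A8, MUC5B, FGG and MMP7 were also lower. Of the 26 lists 9 were called, and 0 with an estimated correlation. Among the 9 was DNA replication, shifted higher (camera adjusted p = 0.00071, but adjusted p = 0.25 with an estimated correlation). Interferon response was another, with 25 of 28 members above the median of all genes (adjusted p = 0.0033, but adjusted p = 0.34 with an estimated correlation). The share of called genes that were higher was 99.1% as deposited, 51.3% after median centring, 62.0% after stretching and 48.1% after quantile normalization, so this split depends on the scaling, and group and set of arrays cannot be told apart.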

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

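The comparison of EGFR with CDH1 in ERC4 and both tests of RNA degradation were chosen only after the results they bear on were seen. The other tests reported here were fixed before their results were seen.

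The fall of epithelial genes in ERC4 and EGFRsh was weighed first. Cells of another type would dilute every HCC827 transcript that they lack, but in ERC4 the EGFR log2 fold change lay 2.96 ± 0.12 (SE) above that of CDH1. In EGFRsh the median of the 10 measured genes nearest to EGFR lay 6.32 above CDH1. The SD of these genes over the square root of their number was 0.22, a spread between genes and not between arrays. This met the bound but cannot decide on dilution, since cells of another type may express these genes too and would then not lower them. The median fall in EGFRsh exceeded the larger control 3' to 5' shift by 1.90, slightly more than the list's interquartile range of 1.81. Degraded RNA nevertheless stays open, since the ACTB and GAPDH controls do not bound the loss of signal for other transcripts. The epithelial list was fixed before the data were examined, and its fall was measured in both kinds of cells. That the cells themselves lost epithelial expression stays a hypothesis. In ERC4 the comparison with CDH1 was chosen after the result was seen, and in EGFRsh dilution and degraded RNA stay open.

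The lower interferon genes in EGFRsh than in NT were weighed next. If the non-target vector had raised them in NT, the list would lie at least 0.5 above the median of all genes in NT minus parental, and it lay 1.54 above, or 1.23 after quantile normalization. Although that meets the bound set in advance, with 25 of 28 members above the median of all genes, the list's call in NT minus parental (adjusted p = 0.0033) was lost with an estimated correlation (adjusted p = 0.34). Of 10000 random lists matched on parental level, 0 lay as high in NT minus parental (highest 0.8). In EGFRsh minus parental, the interferon list lay only 0.31 above the median of all genes. However, NT and EGFRsh both lie in another set of arrays than parental cells, so vector and set cannot be told apart. Degraded RNA stays open as well, since the fall exceeded the control shift by 0.76, less than the interquartile range of 1.64.

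The lower EGFR transcript in EGFRsh could come from loss of the chromosome region, which in this line is known to be amplified. The 10 measured genes nearest to EGFR, by gene order in GRCh38.p14, had a median log2 fold change of 0.04 (SD 0.71), above the bound of -0.5, as were 9 of the 10 genes, with 1 called lower and 3 higher. This argues against loss of a region that spans these neighbours, although COBL, singled out after its value was seen, had a log2 fold change of -2.07. The neighbours were taken by gene order and not by distance, so a smaller loss around EGFR would be missed. An effect of the shRNA on the transcript, which the design names, remains as a hypothesis.

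For EGFR, the shRNA target, the difference of effects (1.51) mostly restates the fall in EGFRsh. Effects also differed between the arms, by the test of the difference itself, for 10 lists. With an estimated correlation 5 of these calls held, and those for mitosis (adjusted p = 0.3), DNA replication (adjusted p = 0.11), glycolysis (adjusted p = 0.28), interferon (adjusted p = 0.11) and YAP target genes (adjusted p = 0.11) were lost. The median differences were 1.07 for epithelial, 0.32 for mitosis, 0.83 for DNA replication, 0.48 for cholesterol synthesis, 0.18 for glycolysis and 1.49 for interferon genes. They were -0.74 for mesenchymal, -0.87 for NF-kB, -0.57 for TGF-beta and -0.41 for YAP target genes. Single genes with opposite changes and large differences were PEG10 (6.26), GPNMB (6.18), KRT4 (4.91), CXCL1 (-5.24) and CXCL6 (-6.49). Of these, GPNMB was also among the highest and CXCL6 among the lowest genes in NT minus parental, so the NT control may contribute. Over all genes the difference was called for 5936 of 11963 (49.6%). It was called for 169 of the 196 genes named by the rule, a high share by construction since they were picked for large changes.

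Signals outside the named genes also differed. The 3' minus 5' control signal shifted in EGFRsh by 0.87 for ACTB and 0.35 for GAPDH, and in ERC4 by -0.15 for GAPDH. Hybridisation controls, which are added to the sample and do not come from the cells, differed by -1.59 in ERC4 and 0.60 in EGFRsh. Of 3151 probe sets with several or no gene symbols, 111 were called with at least 2-fold in ERC4 and 171 in EGFRsh.

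Within each comparison of 3 arrays with 3, the 10 splits are too few for a share under 0.05. Only 1 of 10 splits, the real one, gave as many calls for ERC4 (6902, highest other 0), for EGFRsh (5966, highest other 0) and for NT (11551, highest other 0). For the difference of effects, 2 of 100 drawn splits gave at least the real 5936 calls. The other one, with 7506, is the real split with NT and EGFRsh exchanged, which tests the sum of both effects and so points to a structure of the samples. For calls shared in direction, 1 of 100 splits, the real one, reached 2662 (highest other 1155, with NT and EGFRsh exchanged). Splits that mix groups put their effects into the residual spread, and 81 of the 100 gave 0 calls for the difference and 98 gave 0 shared calls. Only 2 splits keep both groupings, which are too few for a share under 0.05.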

How the results depend on the processing

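Quantile normalization within sets, no pseudocount, stretched values and list tests on 6 arrays were chosen after seeing the data. Counts of calls stayed within 1.5 times under all settings run except these. With every probe set tested on its own, which tests more features, 10518 were called in ERC4, 9411 in EGFRsh (1784 of at least 2-fold), 18319 in NT (12220) and 9276 for the difference (2180). NT genes of at least 2-fold numbered 1662 after quantile normalization over 12 arrays, 2553 after centring and 2301 after stretching, and ERC4 genes 1150 after stretching, which widens that set by construction. Gene list calls fell from 37 to 13 with an estimated correlation. EGFR in ERC4 lost its call at 0.16 and 0.17 after quantile normalization over 12 arrays and within sets (the cause was not tested) and, at 0.21, under a threshold of 0.01. Leaving out 1 array gave it 0.16 to 0.25, with the call lost without parental replicate 2 (0.19) and ERC4 replicate 2 (0.16). PFKFB3 (-0.02) and PSMB10 (0.00) changed sign and lost their calls in ERC4 after both quantile settings. With the mean of probe sets, BAX in ERC4 (0.18) and CCNE2 in EGFRsh (-0.09) also changed sign and lost their calls. Only TYMS in EGFRsh (-0.19), with the mean of probe sets, was called in the opposite direction. The cause of these changes was not tested. Other named gene effects kept direction and side of the threshold in 12451 cases, with 162 weaker and 120 stronger, and lists in 1980, with 67 weaker and 7 stronger. With 1 array left out, calls ranged from 6063 to 6888 in ERC4, 5387 to 6206 in EGFRsh and 5497 to 6002 for the difference. The replicate block gave 6802 calls in ERC4 (6696 of them called without it), 5890 in EGFRsh (5813), 5859 for the difference and 36 lists. Deviations from the group means correlated at -0.12 to 0.07 between same-numbered arrays of the compared groups, so no pairing by number was seen. Signal near background limits dim genes.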

Other observations

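The hepatocyte marker list was written after the fibrinogen and albumin results were seen, but before its own test, and both tests below were fixed before their results were seen. The recounts with FGB, FGG and ALB were chosen afterwards.

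Several gene groups were not called in either cell type, among them ERBB genes (adjusted p = 0.9 in ERC4 and 0.41 in EGFRsh), bypass kinase genes (0.37 and 0.45) and fibroblast and endothelial genes (0.058 and 0.93). The last of these lists was called in ERC4 without parental replicate 2 (adjusted p = 0.03) or without ERC4 replicate 2 (0.049), with members shifted lower. MAPK output genes were higher in 9 of 18 cases in ERC4 (adjusted p = 0.37). Antigen presentation genes gave adjusted p-values of 0.65 in ERC4 and 0.49 in EGFRsh, NRF2 targets 0.45 and 0.14, p53 targets 0.52 and 0.55, and PI3K and FOXO targets 0.65 and 0.82. BCL2 family genes gave 0.52 and 0.93, stem-like and drug efflux genes 0.29 and 0.63, immediate early genes 0.82 and 0.41, and neuroendocrine genes 0.24 and 0.48. Single members still moved: the drug efflux transporter gene ABCB1 had log2 fold changes of 1.69 in ERC4 and 1.46 in EGFRsh, and the NRF2 targets UGDH and HMOX1 rose by 2.47 and 1.88 in ERC4.

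Other lists were called in 1 of the comparisons at the preset correlation. Called in EGFRsh and not in ERC4 were mesenchymal (adjusted p = 0.53 in ERC4), cholesterol synthesis (0.45), interferon response (0.68), NF-kB (0.32) and TGF-beta genes (0.56). Called in ERC4 and not in EGFRsh were mitosis (adjusted p = 0.17 in EGFRsh), glycolysis (0.6), squamous and basal (0.076), unfolded protein stress (0.15) and leukocyte genes (0.82). The difference itself was not called for squamous and basal (adjusted p = 0.9), stress (0.1) and leukocyte genes (0.24), and squamous and basal genes were called in EGFRsh too once dim genes were left out (adjusted p = 0.015). The calls of these 5 lists in ERC4, and that of the interferon list in EGFRsh, were lost with an estimated correlation, at adjusted p-values from 0.089 to 0.3.

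FGG and ALB rose in ERC4, as did FGB, another fibrinogen gene (5.27-fold), and hepatocyte-like cells in these cultures would raise the other abundant hepatocyte transcripts too. The median of 21 other markers was -0.29, with 4 called higher, RBP4 the most at 4.07-fold, and 13 lower. With FGB added it was -0.28, with 5 of 22 higher, and with FGG and ALB too it was -0.24, with 7 of 24 higher. Cells of that type would bring their abundant transcripts together, and the median under the bound of 0.5 set in advance argues against them, although part of the markers rose. No biological explanation was tested.

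Neighbouring genes may have moved together in ERC4 through gain of a chromosome segment. Along the gene order of GRCh38.p14, the largest median over 15 neighbouring measured genes was 1.26, from NAALAD2 to CEP57, with 11 of 15 called higher, and 0 of 1000 shuffled orders reached it (highest 1.11). This is consistent with a gain of that segment, a hypothesis that shared regulation of neighbours would meet as well. In EGFRsh a window from PHKA2 to EIF2S3 reached 1.11, against 1.04 in shuffled orders.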
